A study of Sus scrofa with 6 samples.

How the data were processed

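Single-cell RNA sequencing data of 6 libraries were taken from the deposited count matrices. Per the labels, each came from unsorted cells of red duroc pig skin: normal skin, irradiated skin, and irradiated skin with a 1 mg deferoxamine patch as pretreatment (2 weeks before radiotherapy), continuous (18 weeks in total), chronic (4 weeks after recovery) or acute (12 weeks of recovery after radiation) treatment. Tissue was digested with collagenase and libraries were made with the 10x Chromium 3' v3 chemistry and sequenced on a NextSeq 500, per the labels' protocols. The authors processed reads with Cell Ranger and Seurat 5.0.1 against the pig build Sscrofa11.1, per the submitters' processing notes. The deposited matrices hold counts, namely UMIs per gene and barcode, written by Cell Ranger 6.0.0 per the file headers. No deposited barcode held fewer than 500 UMIs.

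All 32285 gene features of all 6 matrices were mouse Ensembl identifiers, against the pig labels and build. The mouse build and annotation release were not given. The matrices labelled normal, irradiated, acute and chronic also held counts of 4 anti-mouse hashtag antibodies. As no source linked tags to animals, each matrix was treated as 1 sample and antibody UMIs were kept out of gene totals. Nothing was relabelled.

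Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. Doublets were removed per library with Scrublet in scanpy 1.11.5, at its own threshold. Where this marked under 0.5% of cells, as in pretreatment (0.267%) and chronic (0.0109%), the highest-scoring cells were removed instead, at 0.8% per 1000 barcodes up to 10%. Removed shares were 10.8% in normal, 22.0% in irradiated, 1.47% in pretreatment, 2.32% in continuous, 27.4% in acute and 7.78% in chronic. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes (libraries as batches) were scaled, with values held at 10. Then 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9, resolution 1, 2 iterations) gave 24 clusters of all libraries together, without integration. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, matplotlib 3.10.9 and R 4.3.3.

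Clusters were named from marker lists of 20 cell types. A type needed at least 3 markers at 50 CPM or more and 2-fold or more over the median of the other clusters (5 CPM added), and the one with the most markers among the 10 genes highest by that fold gave the name. A cluster with more markers of another type among those 10 genes, led by an erythroid gene, or shallow without leading markers stayed unnamed, which applied to 1 cluster, led by Alas2 and with neutrophil markers. The pig MHC class II markers of dendritic cells matched no mouse symbol, so the MHC class II-led clusters 11 and 12 took the macrophage or monocyte name. This naming rule was revised several times after cluster genes and cluster sizes per library had been seen, and before any ratio of genes was computed. It first counted markers among the 50 highest genes, then markers above the median of other clusters, then left unnamed any cluster led by a marker of another type. Names carry the ending -like, and a class needed 50 cells in both libraries, which left pericyte or smooth muscle-like cells out of the pretreatment and chronic comparisons.

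Marker lists and 21 gene lists, written for pig before the data were examined, were matched to mouse symbols regardless of case. Unmatched members count as unmeasured: 11 of 25 MHC class II genes, 31 of 43 interferon genes and 12 of 26 mitochondrially encoded genes were matched. UMIs were summed per class and library and scaled to CPM, and intervals for ratios are exact at 95% for Poisson counts. A list value is the median log2 ratio of members with at least 20 UMIs over both sums, with an interval from 1000 Poisson redraws. Its percentile is taken among 10000 random lists matched on expression in 20 bins. Shares carry Clopper-Pearson intervals, and the interval of a difference combines the distances of both shares to their bounds as the root of the sum of squares.

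With 1 library per label no test between groups was possible, and no p-value is given. The 5 comparisons were irradiated against normal and each patch schedule against irradiated. In fibroblast-like cells the 5 genes with the highest and the 5 with the lowest ratio are named, and 2 and 2 in vascular endothelial-like, keratinocyte-like and macrophage or monocyte-like cells. Genes needed 100 UMIs and 50 CPM in the higher library, intervals that do not overlap, a symbol, and a CPM of at least 0.25 times that of the highest class in that library. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes were excluded. Up to 2 highest and 2 lowest members of each list qualified too, of which the text prints a part chosen after their values were seen, and Vegfa, Tfrc, Fth1, Cdkn1a, Col1a1, Col3a1 and Acta2 are always given. A count of 0 is set against a floor of 3 UMIs over the class, as a bound. Ratios and list medians were tested on simulated data with 200 genes changed by known folds.

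Depth sets the precision: the fibroblast-like sums held from 2984862 UMIs in chronic to 9590662 in normal. The median log2 ratio of all genes was beyond 0.1 in the pretreatment comparison for vascular endothelial-like (-0.12), keratinocyte-like (-0.22) and macrophage or monocyte-like cells (0.21, or -0.14 with TMM). It was also beyond 0.1 in keratinocyte-like cells of chronic (-0.19) and in neutrophil-like cells of irradiated against normal (-0.26), continuous (-0.45) and acute (0.22). Percentiles among random lists are relative to this shift.

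Alternatives fixed before the data were examined were a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, resolutions 0.5 and 2, each library clustered alone, TMM scaling (edgeR 4.0.16), cells thinned to 1000 UMIs, and a minimum of 100 UMIs for list members. Chosen after seeing the data were each fibroblast-like cluster alone, neutrophil-like cells left out of the denominator, their share among cells with at least 3000 UMIs, the fibroblast-like clusters at resolution 2, and the neutrophil-like class itself. Col1a1 outside fibroblast-like and S100a9 outside neutrophil-like cells gauged free RNA, but own expression could not be told apart. One list member that the naming rule covers is not reported here. Left out were a correction for free RNA, splitting by hashtag, and sequence reads, which were not examined.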

Results

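The labels and the files of this series disagreed on the organism. The labels named skin of red duroc pigs (Sus scrofa), irradiated and given a deferoxamine patch on different schedules, but all 32285 gene features in each library were mouse Ensembl identifiers. The libraries labelled normal, irradiated, acute and chronic also held counts of 4 anti-mouse hashtag antibodies, and the series title named an anti-JUN therapeutic and adhesions after surgery. Each library is therefore called by its label, and no difference is put down to radiation or to deferoxamine, an iron chelator.

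Single-cell RNA sequencing covered 6 libraries, 1 per label and so without replicates. The libraries labelled normal, irradiated, pretreatment, continuous, acute and chronic held 18869, 23022, 1811, 9862, 25052 and 9721 barcodes. Their gene UMIs (unique molecular identifiers) came to 41136493, 54966435, 18611144, 41423107, 49408533 and 37470412 in the same order. The median barcode held 1356, 1572, 7040, 3023, 1339 and 2610 UMIs. After filters and doublet removal, 15794, 17253, 1477, 8709, 17519 and 8466 cells were kept.

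Neutrophil-like and macrophage or monocyte-like cells made up most cells of 5 of the 6 libraries. Neutrophil-like cells took 39.9% of kept cells in the library labelled normal, 36.5% in irradiated, 36.0% in continuous, 26.9% in acute and 26.3% in chronic, but 2.10% (1.43 to 2.97) in pretreatment. Macrophage or monocyte-like cells took 27.2%, 36.6%, 12.3%, 27.0%, 43.3% and 34.0% in the order normal, irradiated, pretreatment, continuous, acute and chronic. Fibroblast-like cells took 13.2%, 7.35%, 37.5%, 8.32%, 7.89% and 4.36% in that order, and T cell-like cells 6.39%, 8.83%, 8.06%, 10.9%, 11.7% and 21.2%. The macrophage or monocyte-like class included clusters 11 and 12, led by the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1, which held 10.8% to 17.6% and 19.8% to 36.1% of it over the 6 libraries and can include dendritic cells. Fibroblast-like cells formed 2 clusters. Cluster 4 was led by Col3a1 (ENSMUSG00000026043), Serping1, Rarres2, Sparc and Dcn and cluster 5 by Serpina3n, Dcn, Lum, Aebp1 and Mfap4. Cluster 5 held 23.0% of the fibroblast-like cells in normal, 25.3% in irradiated, 77.3% in pretreatment, 52.3% in continuous, 31.3% in acute and 42.8% in chronic.

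**Figure D1:**
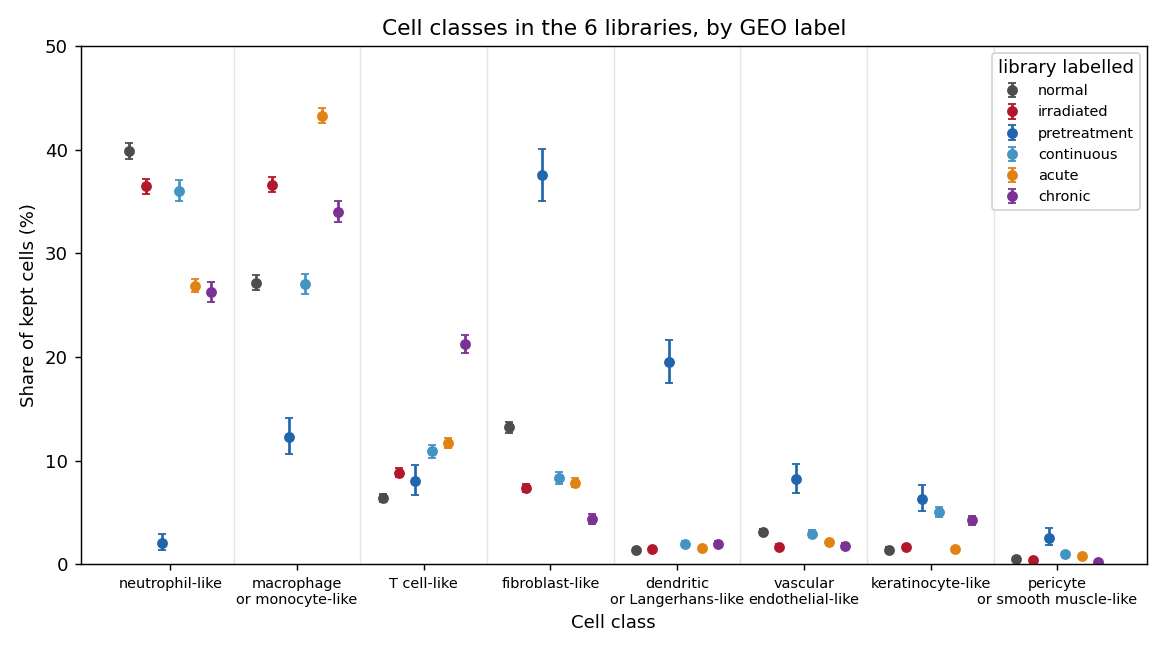
Share of kept cells (%) in 8 cell classes for the 6 libraries, named by label, with 95% Clopper-Pearson bars for counting error only. Pretreatment has 2.10% neutrophil-like and 37.5% fibroblast-like cells, and irradiated 36.5% and 7.35%.

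Gene values are CPM of the UMIs summed over a class in a library, and a fold is the ratio of 2 such values. Brackets hold 95% intervals for counting error only, which leave out any spread between animals, so no test was made and no gene was called changed. A gene list is given by the median log2 ratio of its members and by its percentile among 10000 random lists of like expression. Members are counted as higher or lower from a 1.5-fold difference on. In vascular endothelial-like, keratinocyte-like and macrophage or monocyte-like cells, the lists printed were chosen after their values were seen.

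By the labels, the first comparison sets irradiated skin against normal skin. The library labelled irradiated had a lower share of fibroblast-like cells than the library labelled normal, a difference of -5.88 (-6.54 to -5.22) percentage points, and a higher share of macrophage or monocyte-like cells, a difference of 9.44 (8.44 to 10.4) points, or 5.80 under the stricter cell filter and 6.06 with doublets kept. Inflammatory NF-kB genes stood higher in fibroblast-like, vascular endothelial-like, keratinocyte-like and macrophage or monocyte-like cells, and interferon genes in fibroblast-like, vascular endothelial-like and macrophage or monocyte-like cells. Proliferation, Wnt and mitochondrially encoded genes stood lower in fibroblast-like cells. The extracellular matrix list was close to 0 in fibroblast-like cells as a whole, although the major collagen genes Col1a1 (ENSMUSG00000001506) and Col3a1 were lower.

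Among single genes in fibroblast-like cells, Ptn (ENSMUSG00000029838), a heparin-binding growth factor, was 8.14-fold higher (6.86 to 9.72). Pappa (ENSMUSG00000028370), a protease that releases insulin-like growth factors, was 3.94-fold higher (3.28 to 4.75), the interferon-induced gene Ifi44 (ENSMUSG00000028037) 3.90-fold higher (3.25 to 4.68), the myeloid growth factor Csf2 (ENSMUSG00000018916) 3.74-fold higher (3.13 to 4.50), and the opioid precursor Penk (ENSMUSG00000045573) 3.65-fold higher (3.24 to 4.12). The secreted matrix protein Spon2 (ENSMUSG00000037379) was 3.41-fold lower (2.96 to 3.95) and Sfrp4 (ENSMUSG00000021319), which binds Wnt ligands, 2.69-fold lower (2.32 to 3.13). The haptoglobin gene Hp (ENSMUSG00000031722) was 2.34-fold lower (2.26 to 2.41), Ccnb1ip1 (ENSMUSG00000071470) 2.29-fold lower (1.96 to 2.67), and the complement regulator Cd55 (ENSMUSG00000026399) 2.13-fold lower (1.94 to 2.34). Other classes held more of some of these RNAs in the same library: keratinocyte-like cells of Ptn, vascular endothelial-like cells of Ifi44 and Ccnb1ip1, and pericyte or smooth muscle-like cells of Hp. Col1a1 was 1.32-fold lower (1.30 to 1.33) and Col3a1 1.42-fold lower (1.41 to 1.43), but within cluster 5 both were higher (log2 ratios 0.49 and 0.34). The cell cycle inhibitor Cdkn1a (ENSMUSG00000023067) was 2.08-fold higher (1.98 to 2.18) in the class and at a log2 ratio of -0.056 in cluster 5. Acta2 (ENSMUSG00000035783), highest in pericyte or smooth muscle-like cells, was 1.17-fold higher (1.05 to 1.30) but at a log2 ratio of -0.13 in cluster 5, and the iron storage gene Fth1 (ENSMUSG00000024661) 1.13-fold higher (1.12 to 1.14). The ratios of Vegfa (ENSMUSG00000023951) and of the transferrin receptor Tfrc (ENSMUSG00000022797), 1.02 (0.967 to 1.08) and 1.09 (0.937 to 1.28), had intervals that span 1.

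The interferon list had a median log2 ratio of 0.63 (0.51 to 0.73, percentile 100) in fibroblast-like cells, with 17 of 30 members higher and 0 lower. Irf7, a regulator of interferon genes, was 2.69-fold higher (2.41 to 3.01) there, although its highest level was in macrophage or monocyte-like cells. The NF-kB list stood at 0.52 (0.48 to 0.54, percentile 100), with 15 of 38 members higher and 0 lower. Lif (ENSMUSG00000034394) was 3.53-fold higher (3.11 to 4.01), but the serum amyloid gene Saa3 was 1.21-fold lower (1.21 to 1.22). Secreted factors linked to senescence stood at 0.38 (0.35 to 0.50, percentile 100), with 16 of 40 members higher and 0 lower. The p53 and DNA damage list stood at 0.15 (0.091 to 0.29, percentile 99.9), with 12 higher and 0 lower of 38, and its member Phlda3 was 2.26-fold higher (1.93 to 2.65). The HIF hypoxia list stood at 0.13 (0.070 to 0.19, percentile 99.7), with 1 higher and 2 lower of 45; Adm (adrenomedullin), also an angiogenesis gene, was 1.78-fold higher (1.64 to 1.93). Lists of oxidative stress (0.21, percentile 100.0, 4 higher and 0 lower of 32), antigen presentation (0.47, percentile 100.0, 4 higher and 0 lower of 10), macrophage scavenging (0.28, percentile 100, 6 higher and 1 lower of 27) and angiogenesis genes (0.12, percentile 99.6, 7 higher and 6 lower of 43) also stood above the central 95% of random lists.

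Proliferation genes stood lower in fibroblast-like cells, at -0.41 (-0.50 to -0.33, percentile 0), with 0 of 43 members higher and 14 lower; Kif23 was 2.22-fold lower (1.52 to 3.32) and Ccnb2 1.98-fold lower (1.51 to 2.63). The mitochondrially encoded list stood at -0.46 (-0.49 to -0.43, percentile 0), with 0 higher and 2 lower of 12 at 1.5-fold. The fibroblast subtype list stood at -0.28 (-0.33 to -0.093, percentile 0), with 5 higher and 9 lower of 37, but at 0.023 in cluster 5. Wnt genes stood at -0.24 (-0.39 to -0.16, percentile 0.110), with 1 higher and 9 lower of 36; Wnt16 was 3.93-fold lower (2.27 to 7.23). The immediate early list stood at -0.11 (-0.15 to -0.087, percentile 0.150), with 1 higher and 4 lower of 37, and Fosb was 1.88-fold lower (1.83 to 1.94). The extracellular matrix and collagen list stood at -0.033 (-0.082 to -0.0028, percentile 5.87), with 2 higher and 6 lower of 53: Col8a1 was 2.61-fold higher (2.39 to 2.86) and Col15a1, highest in vascular endothelial-like cells, 2.35-fold lower (2.09 to 2.65). In cluster 5 alone that median was 0.36, against -0.12 in cluster 4. Lists inside the central 95% of random lists were contractile and TGF-beta genes (-0.023, 5 higher and 3 lower of 40), matrix proteases (-0.068, 3 higher and 2 lower of 29), iron handling (0.066, 1 higher and 3 lower of 32), heat shock (0.096, 2 higher and 1 lower of 26), keratinocyte differentiation (-0.092, 4 higher and 4 lower of 14) and keratinocyte basal genes (0.060, 6 higher and 4 lower of 24). Thinning each cell to 1000 UMIs turned the matrix protease median to 0.098, and cluster 5 alone turned the heat shock median to -0.44.

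In vascular endothelial-like cells the interferon regulator Irf7 was 3.34-fold higher (2.44 to 4.59) and the stress cytokine Gdf15 3.26-fold higher (2.63 to 4.06), both highest in macrophage or monocyte-like cells, whereas the lymphatic markers Ccl21a and Mmrn1 were 10.7-fold lower (6.69 to 18.3) and 9.49-fold lower (4.88 to 21.1). No cluster of all libraries together was named lymphatic endothelial or hair follicle. Lymphatic and hair genes here and below can therefore reflect such cells within other classes. With libraries clustered alone, the log2 ratio of Ccl21a in vascular endothelial-like cells turned to 3.33. The NF-kB list stood at 0.56 (0.49 to 0.71, percentile 100) there, the interferon list at 0.21 (0.16 to 0.44, percentile 99.3), the HIF list at 0.14 (-0.018 to 0.18, percentile 96.5) and the angiogenesis list at 0.098 (0.012 to 0.21, percentile 90.4), or -0.0042 with doublets kept. In keratinocyte-like cells the hair follicle keratin Krt75 was 46.8-fold higher (15.8 to 229) on 211 against 3 UMIs and Prr9 22.3-fold higher (11 to 52.1), and the keratins of differentiating epidermis Krt10 and Krt1 were 5.01-fold lower (4.02 to 6.29) and 3.89-fold lower (3.31 to 4.59). Proliferation genes stood at -0.74 (-0.87 to -0.57, percentile 0) in that class, NF-kB genes at 0.27 (0.14 to 0.35, percentile 100.0), differentiation genes at 0.042 (-0.045 to 0.21, percentile 68.8) and basal and wound genes at -0.042 (-0.068 to 0.078, percentile 25.1). S100a9 in that class was 9.18% of its neutrophil-like level in normal, 8.28% in irradiated, 2.98% in continuous, 8.69% in acute and 7.45% in chronic. In macrophage or monocyte-like cells antiviral Rsad2 was 4.27-fold higher (4.03 to 4.54) and Irf7 3.83-fold higher (3.50 to 4.2), but Ctsk, a protease highest in fibroblast-like cells, was 6.62-fold lower (5.86 to 7.5) and U90926 (ENSMUSG00000029409) 4.56-fold lower (3.86 to 5.42). Their interferon list stood at 1.06 (0.98 to 1.18, percentile 100), with 23 of 30 members higher and 0 lower, the NF-kB list at 0.55 (0.48 to 0.59, percentile 100), the scavenging list at 0.15 (0.071 to 0.26, percentile 99.9) and the HIF list at -0.17 (-0.23 to -0.12, percentile 1.58). The Ccl8-led and C1q-led cluster 13 held 22.3% of these cells in irradiated and 11.4% in normal. Contractile genes in pericyte or smooth muscle-like cells stood at 0.12 (-0.011 to 0.30, percentile 91.1).

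Vascular endothelial-like cells differed by -1.45 (-1.79 to -1.11) points of all cells, keratinocyte-like by 0.244 (-0.0274 to 0.515), dendritic-like by 0.0914 (-0.170 to 0.352), or -1.54 under the stricter filter, and pericyte or smooth muscle-like by -0.0987 (-0.258 to 0.0577), or -0.322 with doublets kept and 0.324 with each library clustered alone. Neutrophil-like cells differed by -3.41 (-4.47 to -2.36) points, or -0.626 under the stricter cell filter, and took 29.7% against 29.2% of cells with at least 1000 UMIs. T cell-like cells differed by 2.44 (1.86 to 3.01) points, which turned to -2.07 under the stricter cell filter and was 1.04 at cluster resolution 0.5. With neutrophil-like cells left out of the denominator, the fibroblast-like difference grew to -10.4 points.

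**Figure D2:**
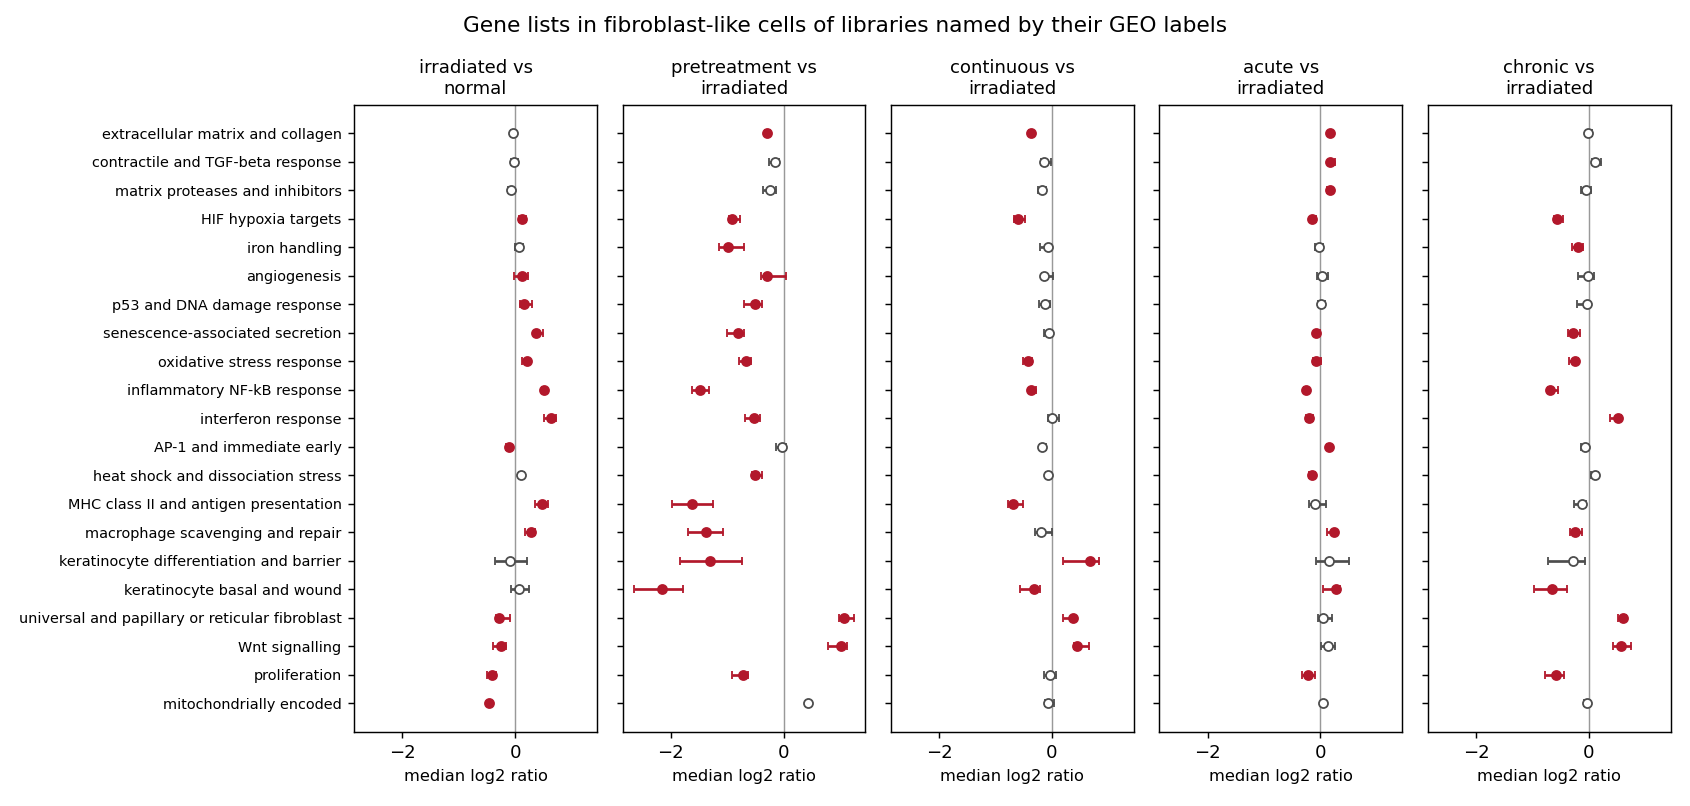
Median log2 ratio of 21 gene lists in fibroblast-like cells for 5 comparisons of libraries named by label; bars are 95% counting intervals, filled red points lie outside the central 95% of random lists, and open points inside. The interferon list is at 0.63 for irradiated against normal, and the NF-kB list runs from 0.52 there to -1.47 for pretreatment against irradiated.

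The library labelled pretreatment, by its label a 1 mg patch 2 weeks before radiotherapy, had the lowest Spearman rho with the library labelled irradiated in all 4 classes compared, 0.870 in fibroblast-like cells. The share of fibroblast-like cells differed by 30.2 (27.7 to 32.7) percentage points and that of neutrophil-like cells by -34.4 (-35.4 to -33.3), or -21.0 under the stricter cell filter. Its fibroblast-like cells held more RNA of Wnt and fibroblast subtype genes and less of NF-kB, senescence-linked, HIF, iron handling and proliferation genes. NF-kB genes also stood lower in vascular endothelial-like, keratinocyte-like and macrophage or monocyte-like cells. The extracellular matrix list was lower in the class but not in each of its clusters.

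In fibroblast-like cells the adhesion gene Cdh4 (ENSMUSG00000000305) was 62.8-fold higher (33.9 to 132), the steroid dehydrogenase Akr1c14 (ENSMUSG00000033715) 40.5-fold higher (21.8 to 85.2), the aldehyde dehydrogenase Aldh3a1 (ENSMUSG00000019102) 29.7-fold higher (18.9 to 49.8), the cytochrome P450 gene Cyp2f2 (ENSMUSG00000052974) 29.5-fold higher (23.8 to 37.1), and the lymphocyte-attracting chemokine Ccl19 (ENSMUSG00000071005) 25.9-fold higher (21.9 to 30.7). The protease inhibitor Serpinb2 (ENSMUSG00000062345) was 2542-fold lower (992 to 9330.2) on 4 against 11289 UMIs and the neutrophil-attracting chemokine Cxcl5 (ENSMUSG00000029371) 500.4-fold lower (356 to 727). At resolution 2, looked at after the folds were seen, the fibroblast-like cluster with Lox and Cxcl5 among its leading genes held 0 of 556 fibroblast-like cells in pretreatment, 9.30% in continuous and 14.1% in chronic, against 39.6% in irradiated, 36.6% in normal and 36.9% in acute. The cluster there with Pappa2 (ENSMUSG00000073530) and Wif1 (ENSMUSG00000020218) held 21.8% in pretreatment against 6.15%. Car4 (ENSMUSG00000000805), a carbonic anhydrase, was 2104-fold lower (377 to 83132) on 1 against 2336 UMIs, the growth factor Ereg (ENSMUSG00000029377) 1292-fold lower (357 to 10673) on 2 against 2869 UMIs, and Csf2 225-fold lower (61.9 to 1861) on 2 against 499 UMIs. Of the genes named in every comparison, Vegfa was 2.61-fold lower (2.41 to 2.83), Tfrc 2.5-fold lower (2.01 to 3.12), Fth1 1.49-fold lower (1.47 to 1.51), Cdkn1a 1.11-fold lower (1.06 to 1.16) and Acta2 3.46-fold lower (2.92 to 4.11). Cdkn1a turned to a log2 ratio of 0.30 in cluster 5. Col1a1 was 1.40-fold higher (1.39 to 1.41) and Col3a1 1.17-fold lower (1.16 to 1.18).

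The NF-kB list stood at -1.47 (-1.63 to -1.32, percentile 0) in fibroblast-like cells, with 6 of 38 members higher and 24 lower. Its member Ccl4 was 517-fold lower (281 to 1079), but Ccl4 was highest in neutrophil-like cells, and fibroblast-like cells of the library labelled irradiated held 2.44% of the neutrophil-like S100a9 level. The HIF list stood at -0.91 (-0.97 to -0.78, percentile 0), with 3 of 44 members higher and 27 lower: the lysyl hydroxylase Plod2 was 9.24-fold lower (8.01 to 10.7) and the lactate transporter Slc16a3, highest in neutrophil-like cells, 12.9-fold lower (10.2 to 16.5), whereas Kdm3a was 1.81-fold higher (1.52 to 2.15). Within cluster 5 the HIF median was -0.30. Iron handling genes stood at -0.99 (-1.14 to -0.71, percentile 0), with 3 higher and 17 lower of 32; the siderophore-binding Lcn2 was 16.4-fold lower (15.3 to 17.6) and the iron reductase Cybrd1 13-fold higher (6.36 to 31.1). The senescence-linked list stood at -0.81 (-1.01 to -0.71, percentile 0), with 11 higher and 23 lower of 40, and Igfbp2 was 11.4-fold higher (10.0 to 13.1). For proliferation genes the median was -0.72 (-0.92 to -0.63, percentile 0), with 0 higher and 25 lower of 43, p53 genes at -0.50 (-0.70 to -0.39, percentile 0), with 7 higher and 18 lower of 38, and interferon genes at -0.52 (-0.69 to -0.42, percentile 0), with 2 higher and 14 lower of 30. Oxidative stress genes stood at -0.66 (-0.79 to -0.57, percentile 0), with 3 higher and 17 lower of 32, and heat shock genes at -0.50 (-0.55 to -0.38, percentile 0.0600), with 3 higher and 11 lower of 26.

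Wnt genes stood at 1.02 (0.79 to 1.12, percentile 100), with 25 of 38 members higher and 3 lower: the Wnt enhancer Rspo1 was 15.1-fold higher (10.8 to 21.6) and the inhibitor Sfrp2 8.75-fold lower (7.49 to 10.3). The fibroblast subtype list stood at 1.06 (0.98 to 1.25, percentile 100), with 24 of 37 members higher and 8 lower. The extracellular matrix list stood at -0.29 (-0.32 to -0.25, percentile 0.360), with 16 of 52 members higher and 21 lower; elastin (Eln (ENSMUSG00000029675)) was 6.51-fold higher (6.12 to 6.93), Mfap4 5.63-fold higher (5.35 to 5.93), tenascin C (Tnc) 16.4-fold lower (15.4 to 17.5) and the crosslinking enzyme Loxl3 11-fold lower (8.93 to 14). Its median was 0.17 in cluster 4 and -0.80 in cluster 5. The contractile list (-0.16, percentile 9.49, 8 higher and 12 lower of 38) turned to 0.32 in cluster 4. Angiogenesis genes stood at -0.29, percentile 0.945 (14 higher and 18 lower of 41), matrix proteases at -0.24, percentile 4.28 (8 higher and 14 lower of 30) with Ctsk 4.45-fold higher (4.31 to 4.59), and immediate early genes at -0.030, percentile 40.9 (12 higher and 6 lower of 37). Further lists were low too: antigen presentation -1.62, percentile 0 (0 higher and 7 lower of 10), macrophage scavenging -1.38, percentile 0 (7 higher and 15 lower of 26), keratinocyte differentiation -1.30, percentile 0.0400 (4 higher and 10 lower of 14) and keratinocyte basal -2.15, percentile 0 (1 higher and 18 lower of 21). Mitochondrially encoded genes stood at 0.44, percentile 96.4 (4 higher and 0 lower of 12), and at -0.063 in cluster 5.

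In vascular endothelial-like cells Ccl21a was 46.0-fold higher (28.9 to 78.0), or a log2 ratio of -2.92 with each library clustered alone, and the transcription factor gene Tcf15 15.1-fold higher (8.81 to 28.2). Esm1, a gene of endothelial tip cells, was 129-fold lower (35.5 to 1074) on 2 against 274 UMIs and the cytokine-induced Ubd 122-fold lower (33.4 to 1011) on 2 against 258 UMIs. NF-kB genes stood at -1.51 (-1.74 to -1.20, percentile 0), with 0 of 35 members higher and 25 lower, interferon genes at -0.54 (-0.70 to -0.29, percentile 1.12), angiogenesis genes at -0.45 (-0.60 to -0.28, percentile 2.10) and HIF genes at -0.36 (-0.55 to -0.20, percentile 8.12). In keratinocyte-like cells Cyp2g1 was 346-fold higher (95.2 to 2863) on 516 against 2 UMIs and Akr1c18 107-fold higher (45.7 to 333), whereas the wound keratins Krt6b and Krt6a were 426-fold lower (76.2 to 16858) on 1 against 571 UMIs and 418-fold lower (202 to 1039). The NF-kB list stood at -2.84 (-3.05 to -2.51, percentile 0) and basal and wound genes at -1.80 (-1.96 to -1.65, percentile 0) in that class. Its proliferation median of 0.37 (0.13 to 0.48, percentile 99.8) turned to -0.20 at cluster resolution 2 and -0.32 with each library clustered alone. Its differentiation median of -0.24 (-0.54 to -0.072, percentile 33.7) turned to 0.092 after thinning.

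In macrophage or monocyte-like cells the lectin genes Cd209d and Cd209e were 188-fold higher (143 to 252) and 96.5-fold higher (56.0 to 180.2), the latter highest in dendritic-like cells. Arg1 was 461-fold lower (158 to 2233) on 3 against 10667 UMIs and Nos2 (ENSMUSG00000020826), highest in neutrophil-like cells, at least 121-fold lower on 0 against 2805 UMIs. The cluster of these cells led by Arg1, F13a1 and Mmp12 held 0 of 182 cells in pretreatment and 33.1% in irradiated, and the cluster led by Ccl8 and C1qb held 56.6% against 22.3%. The scavenging list stood at 0.57 (0.52 to 0.62, percentile 99.8), NF-kB genes at -1.66 (-1.94 to -1.47, percentile 0), interferon genes at -1.24 (-1.45 to -1.06, percentile 0) and HIF genes at -0.92 (-1.04 to -0.74, percentile 0). Of all cells, macrophage or monocyte-like cells differed by -24.3 (-26.1 to -22.4) points, dendritic-like by 18.0 (16.0 to 20.1), vascular endothelial-like by 6.48 (5.11 to 8.01), keratinocyte-like by 4.62 (3.42 to 6.0) and pericyte or smooth muscle-like by 2.12 (1.37 to 3.07). Under the stricter cell filter the keratinocyte-like difference was 1.92 and the pericyte or smooth muscle-like 1.21, and with each library clustered alone 1.77 and 1.22. T cell-like cells differed by -0.771 (-2.18 to 0.794) points, or -4.60 with doublets kept, -5.67 without neutrophil-like cells in the denominator and 0.563 under the stricter cell filter. The libraries labelled pretreatment and continuous held no hashtag antibody counts, so preparation and label cannot be told apart in their comparisons with irradiated.

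The library labelled continuous, by its label a patch for 18 weeks in total, held a lower share of macrophage or monocyte-like cells than the library labelled irradiated, a difference of -9.61 (-10.8 to -8.42) points, or -4.10 with doublets kept. Its share of keratinocyte-like cells was higher, with a difference of 3.39 (2.89 to 3.90) points, or 0.898 under the stricter cell filter. As a whole class, its fibroblast-like cells held less RNA of HIF, oxidative stress, NF-kB and matrix genes, Col1a1 and Col3a1 among them, and more of Wnt and fibroblast subtype genes. In macrophage or monocyte-like cells, interferon genes stood higher and NF-kB genes lower. The fibroblast-like share differed by 0.975 (0.278 to 1.69) points, and turned to -2.39 under the stricter cell filter, -0.459 with doublets kept and -0.783 at cluster resolution 0.5.

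The prolactin receptor gene Prlr (ENSMUSG00000005268) was 16.6-fold higher (12.6 to 22.0) in fibroblast-like cells, but at a log2 ratio of -1.05 at cluster resolution 0.5. Pappa2, a relative of Pappa, was 15.0-fold higher (11.9 to 19.1), the anion transporter Slc26a7 (ENSMUSG00000040569) 11-fold higher (8.65 to 14.5), U90926 6.58-fold higher (5.56 to 7.84), and the agouti pigment signal gene a (ENSMUSG00000027596) 6.41-fold higher (5.24 to 7.91). At resolution 2, looked at after these folds were seen, a fibroblast-like cluster with Igfbp3, Pappa2, Slc26a7, Prlr and Wif1 among its leading genes held 27.8% of fibroblast-like cells in continuous, 6.15% in irradiated and 13.9% in normal. Pappa2 stood at a log2 ratio of 2.36 at resolution 0.5. The nitric oxide synthase Nos2 was 26.2-fold lower (20.4 to 34.2), Ptn 18.9-fold lower (14.1 to 25.7), Serpinb2 11.5-fold lower (10.7 to 12.3), Ereg 8.98-fold lower (7.95 to 10.2) and the imprinted RNA H19 (ENSMUSG00000000031) 8.86-fold lower (7.14 to 11). Prlr and Ptn were highest in keratinocyte-like and Nos2 in neutrophil-like cells. Col1a1 was 1.84-fold lower (1.82 to 1.86), Col3a1 1.63-fold lower (1.61 to 1.64), Vegfa 2.26-fold lower (2.10 to 2.45), Tfrc 1.69-fold lower (1.39 to 2.05) and Acta2 1.31-fold lower (1.16 to 1.48), whereas Fth1 was 1.52-fold higher (1.51 to 1.54). Cdkn1a was 1.07-fold lower (1.02 to 1.11), and turned to log2 ratios of 0.11 after thinning and 0.60 in cluster 5.

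The HIF list stood at -0.60 (-0.67 to -0.47, percentile 0) in fibroblast-like cells, with 3 of 44 members higher and 23 lower: Plod2 was 5.34-fold lower (4.76 to 5.99) and the calcium-regulating hormone Stc2 1.57-fold higher (1.25 to 1.98). In cluster 5 its median was -0.10. Oxidative stress genes stood at -0.43 (-0.51 to -0.35, percentile 0), with 1 higher and 14 lower of 32; the cystine transporter Slc7a11, highest in neutrophil-like cells, was 2.83-fold lower (2.5 to 3.20) and Sod2 1.62-fold higher (1.55 to 1.69). For NF-kB genes the median was -0.37 (-0.40 to -0.28, percentile 0), with 2 higher and 15 lower of 38, and Csf3 was 1.75-fold higher (1.65 to 1.87). The extracellular matrix list stood at -0.37 (-0.41 to -0.33, percentile 0), with 4 higher and 21 lower of 53: Loxl4 was 2.18-fold higher (1.54 to 3.11). In cluster 4 its median was 0.032 and in cluster 5 -1.20. Wnt genes stood at 0.45 (0.38 to 0.66, percentile 100), with 17 higher and 4 lower of 38, but at -0.042 in cluster 4; the secreted Wnt inhibitors Notum and Wif1 were 11.5-fold higher (7.36 to 19.0) and 6.32-fold higher (5.21 to 7.70). The fibroblast subtype list stood at 0.38 (0.19 to 0.42, percentile 100), with 14 higher and 4 lower of 36, and matrix Gla protein (Mgp (ENSMUSG00000030218)) was 5.36-fold higher (5.00 to 5.74). Antigen presentation genes stood at -0.70 (-0.78 to -0.52, percentile 0.0500), with 0 higher and 6 lower of 10, and keratinocyte basal genes at -0.32 (-0.57 to -0.22, percentile 0.550), with 4 higher and 11 lower of 23. The keratinocyte differentiation list stood at 0.68 (0.20 to 0.84, percentile 99.9), with 7 higher and 5 lower of 14, and turned to -0.25 at resolution 0.5.

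Inside the central 95% of random lists lay contractile (-0.13, 5 higher and 6 lower of 40), matrix protease (-0.17, 5 higher and 8 lower of 29), iron handling (-0.066, 5 higher and 6 lower of 32), angiogenesis (-0.14, 7 higher and 11 lower of 42), p53 (-0.11, 3 higher and 6 lower of 38) and senescence-linked genes (-0.055, 8 higher and 14 lower of 40). So did interferon (-0.0035, 4 higher and 2 lower of 30), immediate early (-0.17, 5 higher and 3 lower of 37), macrophage scavenging (-0.19, 5 higher and 11 lower of 27), proliferation (-0.031, 3 higher and 2 lower of 43) and mitochondrially encoded genes (-0.062, 0 higher and 0 lower of 12). The heat shock list (-0.077, 1 higher and 2 lower of 26) turned to 0.12 after thinning.

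In vascular endothelial-like cells Ccl21a was 22.2-fold higher (13.9 to 37.8), or a log2 ratio of -3.22 with each library clustered alone, and Mmrn1 15.7-fold higher (8.05 to 34.9), whereas Esm1 was 38.6-fold lower (19.3 to 90.3) and the granule protein Chga 7.59-fold lower (4.39 to 14.1). NF-kB genes stood at -1.01 (-1.17 to -0.77, percentile 0), interferon genes at 0.24 (0.078 to 0.38, percentile 99.8), angiogenesis genes at -0.35 (-0.45 to -0.22, percentile 2.27) and HIF genes at -0.19 (-0.41 to -0.11, percentile 22.8). In keratinocyte-like cells Akr1c18 was 48.3-fold higher (20.6 to 149) and Saa1, highest in fibroblast-like cells, 17.3-fold higher (8.98 to 38.1), and the simple epithelial keratins Krt19 and Krt8 were 71.1-fold lower (34.0 to 179) and 60.8-fold lower (33.6 to 123). Proliferation genes stood at 0.48 (0.39 to 0.73, percentile 100) in that class, NF-kB genes at -0.94 (-1.05 to -0.77, percentile 0) and basal and wound genes at -0.71 (-0.84 to -0.59, percentile 0). Differentiation genes stood at -0.22 (-0.38 to -0.063, percentile 16.8) and turned to 0.14 after thinning. In macrophage or monocyte-like cells the chemokine Ccl8 was 5.07-fold higher (4.97 to 5.19), Cbr2 4.93-fold higher (4.38 to 5.57), Arg1 10.7-fold lower (10.0 to 11.6) and Ckap2l, highest in neutrophil-like cells, 10.4-fold lower (8.65 to 12.5). The Arg1-led cluster held 1.49% of these cells against 33.1%, and the Chil3-led cluster 31.6% against 11.0%. Interferon genes stood at 0.53 (0.45 to 0.60, percentile 100), scavenging genes at 0.36 (0.31 to 0.40, percentile 99.5), NF-kB genes at -0.88 (-0.97 to -0.82, percentile 0) and HIF genes at -0.22 (-0.32 to -0.18, percentile 1.02). Contractile genes in pericyte or smooth muscle-like cells stood at -0.052 (-0.26 to 0.20, percentile 41.4).

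Vascular endothelial-like cells differed by 1.25 (0.845 to 1.67) points of all cells, or 0.506 under the stricter cell filter, and pericyte or smooth muscle-like cells by 0.524 (0.299 to 0.772), or 0.198, and 0.00248 with each library clustered alone. T cell-like cells differed by 2.06 (1.28 to 2.85) points, or 4.94 under that filter, 0.660 with doublets kept and 0.588 with each library clustered alone. Dendritic-like cells differed by 0.451 (0.113 to 0.808) points, which turned to -3.34 under that filter. Neutrophil-like cells differed by -0.443 (-1.69 to 0.804) points, an interval that spans 0, but by 13.9 under that filter, and took 37.5% against 29.7% of cells with at least 1000 UMIs.

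**Figure D3:**
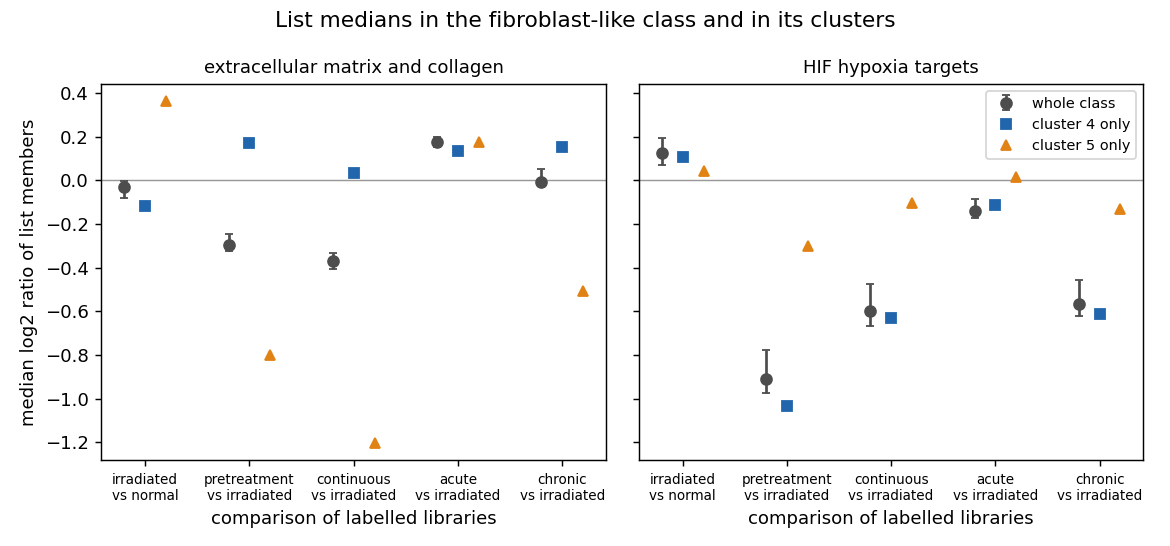
Median log2 ratio of the extracellular matrix list (left) and the HIF list (right) in 5 comparisons of libraries named by label: grey circles for the whole fibroblast-like class with 95% counting intervals, blue squares for cluster 4 and orange triangles for cluster 5. For continuous against irradiated, the matrix list is at -0.37 in the class, 0.032 in cluster 4 and -1.20 in cluster 5.

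The library labelled acute, by its label patch treatment with 12 weeks of recovery after radiation, had the highest Spearman rho with the library labelled irradiated in each class compared. Across genes, their fibroblast-like sums had a rho of 0.988 and their macrophage or monocyte-like sums 0.991; genes are not independent replicates. Its fibroblast-like cells held somewhat more RNA of matrix and contractile genes and less of NF-kB genes. The fibroblast-like share differed by 0.545 (-0.0171 to 1.11) points, an interval that spans 0, or 1.94 under the stricter cell filter.

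In fibroblast-like cells Mgp was 2.70-fold higher (2.5 to 2.91), Eln 2.70-fold higher (2.51 to 2.89), the carboxypeptidase-like Cpxm2 (ENSMUSG00000030862) 2.43-fold higher (2.03 to 2.92), the matricellular Ccn3 (ENSMUSG00000037362) 2.12-fold higher (1.95 to 2.31) and the thrombospondin Thbs4 (ENSMUSG00000021702) 2.02-fold higher (1.82 to 2.25). Csf2 was 2.04-fold lower (1.72 to 2.42), Serpinb2 2.00-fold lower (1.93 to 2.07), the interferon-induced Iigp1 (ENSMUSG00000054072), highest in vascular endothelial-like cells, 1.99-fold lower (1.83 to 2.16), and the cytokines Lif and Il11 (ENSMUSG00000004371) 1.89-fold lower (1.68 to 2.13) and 1.86-fold lower (1.68 to 2.07). In cluster 5, Thbs4 and Serpinb2 turned to log2 ratios of -0.091 and 0.63. Col1a1 was 1.13-fold higher (1.12 to 1.14), Col3a1 1.11-fold higher (1.1 to 1.12) and Fth1 1.14-fold lower (1.13 to 1.16). Acta2 was 1.69-fold higher (1.52 to 1.87) in the class, but at a log2 ratio of -0.098 in cluster 4. Vegfa, Tfrc and Cdkn1a, with ratios of 0.960 (0.902 to 1.02), 1.08 (0.918 to 1.28) and 0.983 (0.940 to 1.03), had intervals that span 1.

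The extracellular matrix list stood at 0.17 (0.15 to 0.20, percentile 100) in fibroblast-like cells, with 6 of 53 members higher and 0 lower; fibromodulin (Fmod) was 3.10-fold higher (2.38 to 4.06). Contractile genes stood at 0.18 (0.15 to 0.26, percentile 100), with 7 higher and 1 lower of 40. Matrix proteases stood at 0.16 (0.12 to 0.21, percentile 100), with 1 higher and 2 lower of 29, and at -0.020 in cluster 5; the inhibitor Timp1 was 1.53-fold lower (1.5 to 1.55). Immediate early genes stood at 0.15 (0.11 to 0.18, percentile 100.0), with 1 higher and 0 lower of 37, and Fos was 1.43-fold higher (1.38 to 1.47). The NF-kB list stood at -0.26 (-0.30 to -0.22, percentile 0), with 0 of 38 members higher and 8 lower, and interferon genes at -0.21 (-0.25 to -0.12, percentile 0), with 1 higher and 0 lower of 30. The HIF list stood at -0.14 (-0.17 to -0.084, percentile 0), with 2 higher and 3 lower of 44, but at 0.015 in cluster 5; Adm was 1.66-fold lower (1.52 to 1.81). For proliferation genes the median was -0.21 (-0.33 to -0.096, percentile 0), with 0 higher and 12 lower of 43, and at 0.27 in cluster 5. Heat shock (-0.15, percentile 0, 0 higher and 0 lower of 26), senescence-linked (-0.081, percentile 0.140, 1 higher and 6 lower of 40) and oxidative stress lists (-0.083, percentile 0.20, 0 higher and 0 lower of 32) stood lower. The macrophage scavenging list (0.24, percentile 100, 4 higher and 1 lower of 27) turned to -0.15 in cluster 5, and the keratinocyte basal list (0.28, percentile 100, 4 higher and 3 lower of 23) to -0.070 with doublets kept.

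Inside the central 95% of random lists lay iron handling (-0.024, 1 higher and 3 lower of 32), angiogenesis (0.031, 0 higher and 3 lower of 42), p53 (0.0096, 0 higher and 2 lower of 38), antigen presentation (-0.096, 0 higher and 0 lower of 10), keratinocyte differentiation (0.15, 4 higher and 0 lower of 13) and fibroblast subtype genes (0.049, 6 higher and 2 lower of 37). Wnt genes (0.13, 2 higher and 0 lower of 37) turned to -0.034 in cluster 5, and mitochondrially encoded genes (0.041, 0 higher and 0 lower of 12) to -0.0093 with TMM scaling.

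In vascular endothelial-like cells the chemokine Cxcl12, highest in fibroblast-like cells, was 1.88-fold higher (1.53 to 2.31) and Mepce, highest in NK or cytotoxic-like cells, 1.85-fold higher (1.35 to 2.55), whereas Ubd was 4.22-fold lower (3.17 to 5.69) and Chga 2.21-fold lower (1.54 to 3.23). Interferon genes stood at -0.27 (-0.40 to -0.10, percentile 0.0100), NF-kB genes at -0.15 (-0.30 to -0.11, percentile 0), angiogenesis genes at 0.022 (-0.036 to 0.13, percentile 55.4) and HIF genes at -0.0031 (-0.11 to 0.10, percentile 48.2). In keratinocyte-like cells the cytokine Il19 was 3.75-fold higher (3.01 to 4.70) and Pi15, highest in pericyte or smooth muscle-like cells, 3.15-fold higher (2.39 to 4.21). Krt19 was 219-fold lower (39.0 to 8696) on 1 against 241 UMIs and the hair follicle keratin Krt71 48.4-fold lower (20.5 to 150.3). Proliferation genes stood at 0.57 (0.43 to 0.69, percentile 100) there, basal and wound genes at 0.29 (0.19 to 0.36, percentile 100), NF-kB genes at -0.35 (-0.40 to -0.24, percentile 0) and differentiation genes at -0.22 (-0.40 to -0.15, percentile 1.28). In macrophage or monocyte-like cells S100a4, highest in dendritic-like cells, was 1.59-fold higher (1.54 to 1.64) and Klf4, highest in keratinocyte-like cells, 1.58-fold higher (1.52 to 1.63). The interferon-induced GTPases Gbp5 and Gbp6 were 3.21-fold lower (2.87 to 3.59) and 2.59-fold lower (2.26 to 2.97), with their highest levels in neutrophil-like and adipocyte-like cells. Interferon genes stood at -0.27 (-0.38 to -0.23, percentile 0) in that class, NF-kB genes at -0.25 (-0.28 to -0.22, percentile 0), scavenging genes at 0.047 (-0.0090 to 0.080, percentile 39.4) and HIF genes at 0.0059 (-0.020 to 0.050, percentile 4.43). Contractile genes in pericyte or smooth muscle-like cells stood at 0.034 (-0.082 to 0.15, percentile 59.8).

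Neutrophil-like cells differed by -9.60 (-10.6 to -8.62) points, vascular endothelial-like by 0.425 (0.132 to 0.719), or 0.739 with doublets kept, keratinocyte-like by -0.225 (-0.491 to 0.0395) and dendritic-like by 0.0746 (-0.187 to 0.336), or 3.04 under the stricter cell filter and 13.1 with each library clustered alone. Macrophage or monocyte-like cells differed by 6.65 (5.62 to 7.68) points, which turned to -13.2 with each library clustered alone, and pericyte or smooth muscle-like cells by 0.393 (0.221 to 0.567), which turned to -0.248. T cell-like cells differed by 2.87 (2.23 to 3.52) points, or -1.0 under the stricter cell filter and 1.78 with doublets kept. Left out of the denominator, neutrophil-like cells turned the fibroblast-like difference to -0.774 points.

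The library labelled chronic, by its label patch treatment at 4 weeks after recovery, held a higher share of T cell-like cells than the library labelled irradiated, a difference of 12.4 (11.4 to 13.4) points, and a lower share of fibroblast-like cells, a difference of -2.99 (-3.57 to -2.39), or -6.27 under the stricter cell filter. As a whole class, its fibroblast-like cells held less RNA of NF-kB, HIF and proliferation genes and more of interferon, Wnt and fibroblast subtype genes. The matrix list as a whole differed little, with Col1a1 and Col3a1 at ratios of 0.996 (0.984 to 1.01) and 1.01 (1.0 to 1.03). NF-kB genes stood lower in vascular endothelial-like, keratinocyte-like and macrophage or monocyte-like cells as well.

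The secreted Wnt inhibitor Wif1 was 9.69-fold higher (7.93 to 11.9) in fibroblast-like cells, Ccl19 5.62-fold higher (4.59 to 6.89), Pappa2 5.42-fold higher (4.12 to 7.19), the serum amyloid gene Saa2 (ENSMUSG00000057465) 4.23-fold higher (3.53 to 5.09) and the Wnt inhibitor Apcdd1 (ENSMUSG00000071847) 3.62-fold higher (2.96 to 4.43). The resolution 2 cluster with Wif1 and Pappa2 among its leading genes held 19.0% of fibroblast-like cells against 6.15%. In cluster 4 alone the log2 ratios of Wif1 and Pappa2 were 0.97 and 0.15. Csf2 was 17.0-fold lower (9.44 to 34.4), the muscle and fibroblast regulator Lmcd1 (ENSMUSG00000057604) 7.23-fold lower (5.01 to 10.8), Car4 5.45-fold lower (4.65 to 6.44) and Ereg 5.31-fold lower (4.60 to 6.15). Ptn was 7.41-fold lower (5.60 to 9.98) in the class, but at a log2 ratio of 0.69 in cluster 4. Vegfa was 1.37-fold lower (1.26 to 1.5), Tfrc 1.46-fold lower (1.14 to 1.89) and Cdkn1a 1.31-fold lower (1.23 to 1.40), and in cluster 5 Vegfa and Cdkn1a turned to log2 ratios of 0.0044 and 0.11. Acta2 was 1.38-fold higher (1.21 to 1.58) and turned to -0.46 in cluster 4. Fth1 had a ratio of 0.987 (0.974 to 1.00) and a log2 ratio of 0.041 in cluster 4. The log2 ratio of Col3a1 turned to -0.062 with TMM scaling and -0.56 in cluster 5.

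NF-kB genes stood at -0.68 (-0.73 to -0.54, percentile 0) in fibroblast-like cells, with 1 of 38 members higher and 20 lower, and complement C3 was 1.74-fold higher (1.69 to 1.78). The HIF list stood at -0.57 (-0.62 to -0.46, percentile 0), with 1 of 44 members higher and 22 lower, and at -0.13 in cluster 5; Plod2 was 2.04-fold lower (1.83 to 2.28) and the mitophagy gene Bnip3 2.27-fold lower (1.94 to 2.68). For proliferation genes the median was -0.59 (-0.77 to -0.44, percentile 0), with 0 higher and 22 lower of 43, but at 0.14 in cluster 5. Interferon genes stood at 0.51 (0.37 to 0.57, percentile 100), with 11 higher and 1 lower of 30, and Ifit3 was 2.83-fold higher (2.27 to 3.53). The fibroblast subtype list stood at 0.60 (0.52 to 0.67, percentile 100), with 19 higher and 2 lower of 36, and Wnt genes at 0.57 (0.43 to 0.75, percentile 100), with 18 higher and 1 lower of 36; the Wnt enhancer Rspo4 was 9.46-fold higher (4.41 to 22.5). The senescence-linked list stood at -0.27 (-0.37 to -0.15, percentile 0), with 3 higher and 14 lower of 40, oxidative stress genes at -0.24 (-0.36 to -0.19, percentile 0), with 1 higher and 8 lower of 33, and iron handling genes at -0.19 (-0.30 to -0.096, percentile 0.400), with 3 higher and 6 lower of 31. The extracellular matrix list stood at -0.010 (-0.028 to 0.051, percentile 34.2), with 5 higher and 7 lower of 53: Tnxb was 1.78-fold higher (1.62 to 1.95) and Tnc 2.88-fold lower (2.76 to 3.0). Its median was 0.15 in cluster 4, -0.51 in cluster 5 and 0.11 with doublets kept. Keratinocyte basal genes stood at -0.66, percentile 0 (0 higher and 11 lower of 19). Macrophage scavenging genes stood at -0.25, percentile 0.13 (4 higher and 9 lower of 26), and turned to 0.037 after thinning.

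Inside the central 95% of random lists lay matrix protease (-0.055, 2 higher and 6 lower of 29), angiogenesis (-0.021, 7 higher and 9 lower of 41), immediate early (-0.072, 2 higher and 1 lower of 37), keratinocyte differentiation (-0.27, 1 higher and 4 lower of 11) and mitochondrially encoded genes (-0.033, 0 higher and 0 lower of 12). Cluster 5 alone turned the contractile list (0.11, 8 higher and 2 lower of 40) to -0.17, the p53 list (-0.030, 2 higher and 6 lower of 38) to 0.056 and the antigen presentation list (-0.12, 1 higher and 4 lower of 10) to 0.012. Resolution 0.5 turned the heat shock list (0.11, 1 higher and 1 lower of 26) to -0.023.

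In vascular endothelial-like cells the granule genes Camp and Ngp were at least 83.2-fold higher (167 against 0 UMIs) and 56.2-fold higher (23.7 to 175). Both were highest in neutrophil-like cells, and class purity was not tested. The metabolic kinase Pdk4, highest in adipocyte-like cells, was 3.69-fold lower (2.36 to 6.04) and the adhesion molecule Vcam1 3.29-fold lower (2.66 to 4.11). For NF-kB genes the median was -1.23 (-1.36 to -0.99, percentile 0), HIF genes at -0.43 (-0.56 to -0.23, percentile 0), angiogenesis genes at -0.10 (-0.31 to -0.020, percentile 52.6) and interferon genes at 0.049 (-0.12 to 0.21, percentile 89.7). In keratinocyte-like cells the hair genes S100a3 and Krt35 were 80.8-fold higher (40.9 to 188) and 23.8-fold higher (12.4 to 52.5), and Krt19 and Krt8 63.4-fold lower (30.3 to 159) and 31.4-fold lower (19.8 to 52.8). Proliferation genes stood at 0.50 (0.41 to 0.67, percentile 100) in that class, NF-kB genes at -1.07 (-1.24 to -0.96, percentile 0), basal and wound genes at -0.31 (-0.38 to -0.17, percentile 4.67) and differentiation genes at 0.028 (-0.077 to 0.15, percentile 89.4). In macrophage or monocyte-like cells the interferon-induced chemokine Cxcl9 was 2.82-fold higher (2.66 to 2.99) and the tRNA synthetase Eprs 2.53-fold higher (2.33 to 2.75), with their highest levels in vascular endothelial-like and T cell-like cells. The chemokine Ccl4 was 5.39-fold lower (5.29 to 5.49) and Ckap2l 5.22-fold lower (4.59 to 5.96), both highest in neutrophil-like cells. NF-kB genes stood at -0.90 (-0.97 to -0.85, percentile 0), interferon genes at -0.35 (-0.41 to -0.26, percentile 0.0100) and HIF genes at -0.28 (-0.33 to -0.23, percentile 0.0200). Scavenging genes stood at 0.10 (0.045 to 0.15, percentile 82.7) and turned to -0.017 under the stricter cell filter. The Arg1-led cluster held 18.1% of these cells against 33.1%, and cluster 12 36.1% against 22.9%.

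Neutrophil-like cells differed by -10.2 (-11.4 to -9.02) points, which turned to 0.234 under the stricter cell filter, and macrophage or monocyte-like cells by -2.63 (-3.87 to -1.38), which turned to 0.619 with doublets kept and was -5.97 at cluster resolution 2. Keratinocyte-like cells differed by 2.58 (2.11 to 3.07) points, or 1.46 under that filter, dendritic-like by 0.459 (0.118 to 0.821), or 1.25 and 3.70 at resolution 2, vascular endothelial-like by 0.0207 (-0.316 to 0.376) and pericyte or smooth muscle-like by -0.180 (-0.330 to -0.0150), or -0.691 with each library clustered alone. All 5 comparisons share the library labelled irradiated, so any error in it enters the first with the opposite sign to the other 4. Genes with near-identical relatives, among them Ccl21a, Saa1, Saa2, Krt6a, Krt6b, Cd209d and Cd209e, may share reads with them, so their values are uncertain.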

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

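All tests of explanations in this part were chosen only after the result was seen. Counts of hashtag antibodies, which no comparison used, stood above 0 in 4 of the 6 libraries: 33849896 antibody UMIs in normal, 41181650 in irradiated, 30643720 in acute and 22083108 in chronic.

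Mouse identifiers stood under pig labels. Pig RNA counted on a mouse annotation would leave genes found in rodents alone near 0, yet 5 of 7 such genes (Ly6a, Ly6c2, Ccl6, Ccl9 and Wfdc17) reached 100 CPM in some class of every library. The exceptions were Ly6g and Retnlg, at 2.59 and 38.0 CPM in their highest class of pretreatment, where neutrophil-like cells, their highest class elsewhere, were too few to be summed. In the 4 libraries with anti-mouse antibodies, the highest tag had a median of at least 486 UMIs per cell, but at the median it was only 1.18 times the second tag in acute and 2.04 times in irradiated, and free antibody could give such counts too. The 5 genes above argue against pig RNA and for mouse tissue. Whether the labels, the files or both are misplaced stays open, as does any biological meaning of the labels.

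Neutrophil-like cells were few in the library labelled pretreatment. Loss of shallow cells at the UMI minimum is argued against, since among cells with at least 1000 UMIs the lowest share in another library was 15.5% (acute), against 1.52% in pretreatment. At 3000 UMIs, however, acute had 2.31% (1.74 to 3.01), which overlaps 1.28% (0.716 to 2.10), while normal had 4.58%, irradiated 6.29%, chronic 6.74% and continuous 23.9%. Preparation without hashtags is argued against as the sole cause by the continuous library, which had none either and held 36.0%. A wrong label, a loss in handling that library alone, and the untested effect of the labelled schedule stay open.

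Neutrophil-like cells made up 39.9% of cells in the library labelled normal, but 23.1% under the stricter filter, where continuous held 36.4%. Swapped labels with irradiated would need a low share there, and it was 36.5%. Retnlg was 17.8-fold higher in neutrophil-like cells than in its highest other class in normal. It led clusters of this class, so it cannot test free RNA. A swap with pretreatment, at 2.10%, cannot be told apart from a correct label, because 1 library per label leaves no second sample to compare. A biological difference under the label normal was not tested and stays open.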

How the results depend on the processing

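Each fibroblast-like cluster alone and the denominator without neutrophil-like cells were chosen only after the result was seen, and the other tests before the data were examined. No paired analysis was possible because each label had 1 library. Share differences, list medians and gene ratios were recomputed under each alternative that applied, but correlations, cluster shares within a class and CPM values were not. This gave 2934 values: 2116 stayed within the counting interval, 745 moved beyond it in the same direction or as an uncalled value, and 73 reversed. For the 15 results fixed in advance, 69 of 100 list values and 13 of 30 share values stayed within it. Counting intervals are narrow and hold no spread between animals. Rare classes are a further limit: under 50 pericyte or smooth muscle-like cells were left in pretreatment and chronic.

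The fibroblast-like share difference ran from -10.4 to -4.39 points for irradiated against normal, 25.0 to 30.3 for pretreatment, -2.39 to 1.45 for continuous, -0.774 to 1.94 for acute and -6.27 to -2.66 for chronic. The matrix list ran from -0.17 to 0.36, -0.80 to 0.17, -1.20 to 0.032, 0.12 to 0.22 and -0.51 to 0.15 in that order. The HIF list ran from 0.043 to 0.16, -1.03 to -0.30, -0.64 to -0.10, -0.19 to 0.015 and -0.65 to -0.13, so its direction held under all alternatives except for acute in cluster 5.

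Every reversed value, and each moved value of the 15 results fixed in advance, follows by setting, as does each share difference that left its interval, turned or moved by over 1.5 times, and is not given beside its result in the report. Outside the results fixed in advance, 317 of 1157 values for genes, 312 of 1442 for lists and 75 of 205 for shares moved, and those for genes and lists and smaller moves of shares are not listed. Comparisons are named by their first library, and lists are in fibroblast-like cells unless another class is given. For each such value the cause was not tested.

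Under the stricter cell filter, the share difference of T cell-like cells was -2.07 for irradiated and -1.0 for acute, that of fibroblast-like cells -8.34 for irradiated, 26.6 for pretreatment, -2.39 for continuous, 1.94 for acute and -6.27 for chronic. That of pericyte or smooth muscle-like cells was -0.263 for irradiated, that of dendritic-like cells -3.34 for continuous. For chronic it was 0.234 for neutrophil-like, -5.17 for macrophage or monocyte-like and -0.335 for vascular endothelial-like cells. The scavenging list in macrophage or monocyte-like cells stood at -0.017 for chronic. With doublets kept, the share difference of fibroblast-like cells was -5.10 for irradiated, -0.459 for continuous and -4.06 for chronic. That of macrophage or monocyte-like cells was 0.619 for chronic. The matrix list stood at -0.17 for irradiated, -0.22 for pretreatment, -0.17 for continuous and 0.11 for chronic. The angiogenesis list in vascular endothelial-like cells stood at -0.0042 for irradiated and the keratinocyte basal list at -0.070 for acute. At cluster resolution 0.5, the share difference of fibroblast-like cells was -4.53 for irradiated, 25.0 for pretreatment and -0.783 for continuous. That of T cell-like cells was 3.17 for continuous. For continuous, the matrix list stood at -0.19, the keratinocyte differentiation list at -0.25 and the log2 ratio of Prlr at -1.05. For chronic, the heat shock list stood at -0.023 and the log2 ratio of Fth1 at 0.0089. At cluster resolution 2, the share difference of dendritic-like cells was -1.74 for irradiated, 1.45 for continuous and 1.33 for acute. The proliferation list in keratinocyte-like cells stood at -0.20 for pretreatment. With each library clustered alone, the share difference of fibroblast-like cells was -4.39 for irradiated and 25.4 for pretreatment, that of dendritic-like cells -0.237 for irradiated and 1.12 for continuous. For acute it was -13.2 for macrophage or monocyte-like and -0.248 for pericyte or smooth muscle-like cells. The proliferation list in keratinocyte-like cells stood at -0.32 for pretreatment and the matrix list at -0.038 for chronic. The log2 ratio of Ccl21a stood at 3.33 for irradiated, -2.92 for pretreatment and -3.22 for continuous and Col3a1 at -0.011 for chronic.

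Without neutrophil-like cells in the denominator, the share difference of fibroblast-like cells was -10.4 for irradiated, 26.7 for pretreatment, -0.774 for acute and -5.66 for chronic. That of vascular endothelial-like cells was -2.57 for irradiated, 1.93 for continuous and -0.346 for chronic. That of macrophage or monocyte-like cells was -45.1 for pretreatment, -15.4 for continuous, 1.52 for acute and -11.6 for chronic. That of T cell-like cells was 3.12 for continuous, that of keratinocyte-like cells 5.28 for continuous and -0.654 for acute. That of pericyte or smooth muscle-like cells was 0.814 for continuous and -0.343 for chronic. That of dendritic-like cells was -0.204 for acute. With TMM scaling, the matrix list stood at -0.0011 for irradiated, -0.35 for pretreatment, 0.12 for acute and -0.093 for chronic. The HIF list stood at -0.19 for acute and -0.65 for chronic and the mitochondrially encoded list at -0.0093 for acute. The log2 ratio of Col3a1 stood at -0.062 for chronic. With cells thinned to 1000 UMIs, the protease list stood at 0.098 for irradiated and the matrix list at -0.43 for pretreatment, -0.55 for continuous, 0.22 for acute and -0.15 for chronic. The keratinocyte differentiation list in keratinocyte-like cells stood at 0.092 for pretreatment and 0.14 for continuous. The heat shock list stood at 0.12 for continuous, the keratinocyte basal list at -0.0051 for acute and the mitochondrially encoded list at -0.060 for acute. For chronic, the scavenging list stood at 0.037, or -0.023 in macrophage or monocyte-like cells. The log2 ratio of Cdkn1a stood at 0.11 for continuous and Col3a1 at -0.097 for chronic.

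In cluster 4 alone, the matrix list stood at -0.12 for irradiated, 0.17 for pretreatment, 0.032 for continuous, 0.13 for acute and 0.15 for chronic. For pretreatment, the contractile list stood at 0.32 and the HIF list at -1.03. For continuous, the keratinocyte differentiation list stood at -0.36 and the Wnt list at -0.042. The heat shock list stood at -0.0033 for chronic. The log2 ratio of Acta2 stood at -0.098 for acute and -0.46 for chronic, Ptn at 0.69 and Fth1 at 0.041 for chronic. In cluster 5 alone, the matrix list stood at 0.36 for irradiated, -0.80 for pretreatment, -1.20 for continuous and -0.51 for chronic. The protease list stood at 0.39 for irradiated and -0.020 for acute and the HIF list at 0.043 for irradiated, -0.30 for pretreatment, -0.10 for continuous, 0.015 for acute and -0.13 for chronic. The heat shock list stood at -0.44 for irradiated and 0.092 for continuous and the fibroblast subtype list at 0.023 for irradiated. The mitochondrially encoded list stood at -0.063 for pretreatment and -0.17 for acute and the scavenging list at -0.15 for acute. The keratinocyte basal list stood at -0.18 for acute, the Wnt list at -0.034 for acute and the proliferation list at 0.27 for acute and 0.14 for chronic. For chronic, the contractile list stood at -0.17, the p53 list at 0.056 and the antigen presentation list at 0.012. The log2 ratio of Cdkn1a stood at -0.056 for irradiated, 0.30 for pretreatment, 0.60 for continuous and 0.11 for chronic. Col1a1 stood at 0.49 for irradiated, Col3a1 at 0.34 for irradiated and -0.56 for chronic and Acta2 at -0.13 for irradiated. Thbs4 stood at -0.091 for acute, Serpinb2 at 0.63 for acute and Vegfa at 0.0044 for chronic.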

Other observations

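The values in this part were chosen after they were seen, and no tests were made on them. Dendritic or Langerhans-like cells made up 19.5% (17.5 to 21.6) of the library labelled pretreatment, 1.39% of normal, 1.48% of irradiated, 1.93% of continuous, 1.55% of acute and 1.94% of chronic. Under the stricter filter, where a cluster led by MHC class II genes also took that name, they made up 24.1%, 13.1%, 11.5%, 8.21%, 14.6% and 12.8% in the same order. Col1a1 RNA in pericyte or smooth muscle-like cells was 10.3% to 44.2% of its fibroblast-like level in the same library and in vascular endothelial-like cells 0.143% to 2.88%. Of its neutrophil-like level, S100a9 RNA was 0.554% to 2.82% in fibroblast-like, 2.98% to 9.18% in keratinocyte-like and 4.69% to 10.3% in Schwann or neural-like cells.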
